A study of Homo sapiens with 3 samples.

How the data were processed

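YBX1 (YB-1) is a cold-shock domain protein that binds DNA and RNA and has roles in transcription, splicing and translation. HEL is an established human erythroleukaemia cell line with a mutated JAK2 gene. Its chromatin was crosslinked with formaldehyde, sheared and immunoprecipitated with an antibody against YBX1, per the labels' protocols, and the recovered DNA was sequenced (ChIP-seq). The series held 3 libraries from untreated cells: 2 YBX1 immunoprecipitations, called replicates 1 and 2 as the labels number them, and 1 input library of sheared chromatin without immunoprecipitation. The labels do not say whether the replicates came from separate cultures, so p-values measure only what these libraries show and their spread may be technical. The name of the replicate 2 alignment in the header of its peak list carries a different number than the label; the label was followed.

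The submitters' processing notes name bcl2fastq 02.14.01.07, Trimmomatic 0.36, Bowtie2, MACS 1.4 and the genome build hg19. Peaks were called with MACS 1.4.2 on each replicate separately against the same input library, per the file headers, and replicates were not pooled. The headers give a p-value cutoff of 1e-05, an effective genome size of 2.70e+09, a band width of 300 bp, a tag size of 36 bp, 1 tag kept per position, and the larger library scaled down to the smaller. The fragment shift d was 20 bp in both runs, which is shorter than a tag. The local background was the highest of the genome-wide level and the input levels over 1000 bp and 10000 bp, per the file headers. The deposited lists had been filtered and annotated by the authors; the rule of that filter is not given in the sources used here.

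Each row of the deposited lists gives a peak with the count of tags in it, per the file headers. The deposited score is the negative log10 of the peak's p-value times 10; its column name was lost in a spreadsheet, and the unit was read from the values, whose minimum matches the cutoff. The fold enrichment is the authors' ratio of ChIP tags at the summit to the local background. The authors' false discovery rate, as a percent, was 0 for all peaks of both lists. The deposited width and summit position are in base pairs, and coordinates are hg19 and count from 1. Fold enrichment and score are the authors' own values for each peak throughout, and they were used to describe, rank or filter peaks, to correlate paired peaks between the lists, and to compare sets of peaks within a list.

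The genome-wide background equals the tags kept times d divided by the effective genome size, so a peak whose input lay at or below that level has a fold enrichment that is a whole multiple of 13.5 in replicate 1 and 13.6 in replicate 2. A peak within 0.006 of such a multiple was counted as lying at the genome-wide background. Chance would place 0.089% of replicate 1 peaks and 0.0882% of replicate 2 peaks within that tolerance.

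A peak was shared when it overlapped a peak of the other list by at least 1 bp. Paired peaks that overlapped were merged into shared regions, whose class and repeat come from the strongest replicate 1 peak and whose tag counts come from the strongest peak of each replicate. The observed overlap was compared with 100 random placements of the replicate 2 peaks on the same chromosomes with their widths kept, which is a one-sided test whose smallest p is 0.0099. Correlations of log2 fold enrichment over shared regions and differences of median log2 fold enrichment were tested with 100000 permutations, two-sided, whose smallest p is 1e-05. Chromosomes were tested with exact binomial tests, two-sided, of shared regions against chromosome length, and gene lists with Fisher's exact test, two-sided, each with Benjamini-Hochberg adjustment. Shares carry 95% Wilson intervals, which cover counting error only.

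Position (promoter, exon, intron, intergenic), genes and repeat elements are the authors' annotation in the deposited lists. No hg19 annotation was used here, and this changed the plan in these respects. A gene was counted when the authors' annotation named it for a peak, in place of a 1 kb window around its start. The background for gene lists was the 10816 genes named in either list, and position shares were described without random placement. Chromosome lengths were taken as the end of the last peak on each chromosome, and unsequenced stretches were not corrected for. For intergenic peaks the annotation names neighbouring genes, often several. Of 10830 symbols in the lists, 9603 were current and 678 were matched through older names in a RefSeq gene table of GRCh38, which was used for names only. Tandem repeat units were grouped over rotations and strands, so that AGAT stands for TCTA, TAGA and their rotations.

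Before the data were examined, 16 gene lists were fixed: signalling by MAPK-ERK and MNK and by JAK-STAT, splicing factors, Y-box and cold-shock domain genes, cytoplasmic ribosomal proteins, translation initiation, erythroid, megakaryocyte and platelet genes, haematopoietic transcription factors, cell cycle and DNA replication, DNA repair, canonical histones, the mitochondrial respiratory chain, and neuronal, hepatocyte and lymphoid genes as lists from other cell types. The rule for named genes was fixed then too: YBX1, JAK2 and MKNK1, up to 4 members of each list with the strongest shared regions, and the 20 strongest shared regions outside Y and unplaced contigs. Strength was the lower of the 2 fold enrichments. Some genes that this rule names are not reported here. Fixed alternatives were a p-value of at most 1e-10, the stronger 50% of each list by fold, a false discovery rate of at most 1%, an overlap of 50% of both peaks, summits within 200 bp, the score as strength, random placement over the whole genome, and all peaks of a single replicate. The stronger 50% means peaks at or above the median fold of their list. Because of ties at the median it held 12874 of 22874 replicate 1 peaks and 9440 of 17285 replicate 2 peaks. Alternatives chosen after seeing the data were a shift of replicate 2 peaks along each chromosome, autosomes without alternative contigs, regions at the genome-wide background in both replicates for the correlation, other gene assignments and backgrounds for the lists, and peaks counted in place of genes. Windows of 5 kb around gene starts, gene length as a covariate and gene numbers per chromosome were planned but not run, because they need an hg19 annotation.

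The overlap test was tested on simulated lists of 6000 peaks: with planted shares of 0%, 25% and 50% it found 0.0333%, 25.3% and 50.4%. Simulated gene lists were part of a set of 12000 genes, in which genes outside the lists had a shared region at a rate of 60%. The list test called 0.667% of lists with the same rate, 8% of lists at 75% and 95.5% of lists at 95%. These lists were larger than the lists tested here, which had 3 to 22 named members, so the rates do not carry over. In the data, the neuronal list did not pass with 15 of 16. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.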

Results

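YBX1 occupancy of chromatin was mapped by ChIP-seq in untreated HEL cells in 2 replicates, each compared with the same input library. The replicate 1 library held 10275569 tags, of which 10010819 were kept after removal of duplicates, and the replicate 2 library held 10190347 tags, of which 9926271 were kept. The input library was deeper, at 77308330 tags and 74780414 kept, which is 7.47 and 7.53 times the ChIP libraries. The series asks where YBX1 sits on chromatin in cells with mutated JAK2, in a study of splicing and of signalling through MKNK1 and ERK.

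YBX1 peaks lay mostly on tandem repeats, and a small share lay at promoters. Replicate 1 had 22874 peaks and replicate 2 had 17285, with median widths of 70 bp and 69 bp. These widths and the folds at summits rest on the caller's fragment shift of 20 bp, which is shorter than a tag, so they do not measure the extent of binding. Simple tandem repeats held 51.2% of replicate 1 peaks and 58.9% of replicate 2 peaks, whereas promoters held 3.28% and 3.42%. These shares were not compared with the share of the genome that each class covers, so neither preference nor avoidance was tested. The peaks rested on few tags: the median was 9 in replicate 1 and 8 in replicate 2, the minimum was 5, and peaks with exactly 5 tags made up 21.7% and 22.1% of the lists. All tags in peaks amounted to 3.85% of the kept tags of replicate 1 over 2253812 bp and to 2.53% of those of replicate 2 over 1570619 bp. Median fold enrichment, the authors' own value for each peak, was 53.9 in replicate 1 and 54.4 in replicate 2. For 38.9% and 37.4% of peaks it is a fold over the genome-wide background and not over the local input. LINE elements held 11.4% and 9.26% of peaks, LTR elements 5.11% and 4.11%, and SINE elements 4.06% and 3.42%. A single LINE type, HAL1-2a_MD, accounted for 774 of the replicate 1 peaks, or 29.7% of all LINE peaks in that list. Peaks without an annotated repeat or CpG island made up 25.7% and 21.3%.

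The first comparison asked how far the replicates named the same regions. Peaks on AGAT tandem repeats were found in the other replicate most often among the 6 most frequent repeat units, for 82.1% of replicate 1 and 94.5% of replicate 2 peaks. Peaks on ACCATC repeats were shared in 68.7% and 90.2% of cases, peaks on ATCC repeats in 63% and 89.9%, and peaks on HAL1-2a_MD elements in 58.4% and 91.3%. Peaks outside any annotated repeat or island were shared in 35.3% and 57.7% of cases, and peaks on SINE elements in 31.2% and 49.7%. Over all classes, 12353 of 22874 replicate 1 peaks (54%, 95% Wilson interval 53.4% to 54.6%) overlapped a replicate 2 peak, and 13416 of 17285 replicate 2 peaks (77.6%, 77% to 78.2%) overlapped a replicate 1 peak. They merged into 10895 shared regions. Random placement on the same chromosomes gave a mean of 0.12% and 0.142%, with a highest value of 0.184% and 0.208% (permutation test, p = 0.0099 for each, the smallest that 100 placements can give). Both lists were called against the same input library and are not independent of each other. The placements did not keep peaks on tandem repeats, so repeats recovered in both libraries for any reason would also exceed them. The test therefore does not measure shared YBX1 binding.

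**Figure D1:**
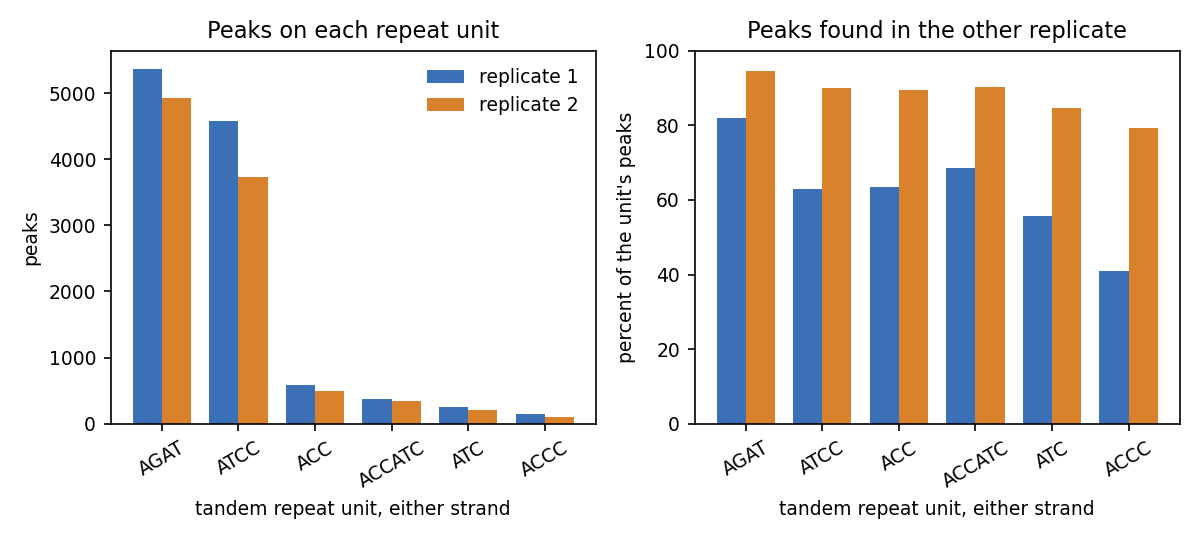
Peaks on the 6 most frequent tandem repeat units (left, number of peaks) and the percent of those peaks that overlapped a peak of the other replicate (right), for replicate 1 (blue) and replicate 2 (orange). AGAT repeats held 5372 and 4930 peaks and ATCC repeats 4579 and 3728, and AGAT peaks were shared most often in both replicates.

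Regions that were strong in replicate 1 tended to be strong in replicate 2. The region in an intron of CFAP61, a gene associated with cilia and flagella, was the strongest by the lower of its fold enrichments, at 342 in replicate 1 and 281 in replicate 2. Over all shared regions, log2 fold enrichment correlated with Pearson's r of 0.767 and Spearman's rho of 0.714 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The correlation is across 10895 regions of 2 libraries, which are not independent replicates; these regions were called in both lists and their folds divide by the same input, so a value above 0 does not by itself measure binding. Over the 3936 regions at the genome-wide background in both replicates, where the local input does not enter the fold, r was 0.585 and rho 0.563 (permutation p = 1e-05 for each, the smallest possible).

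**Figure D2:**
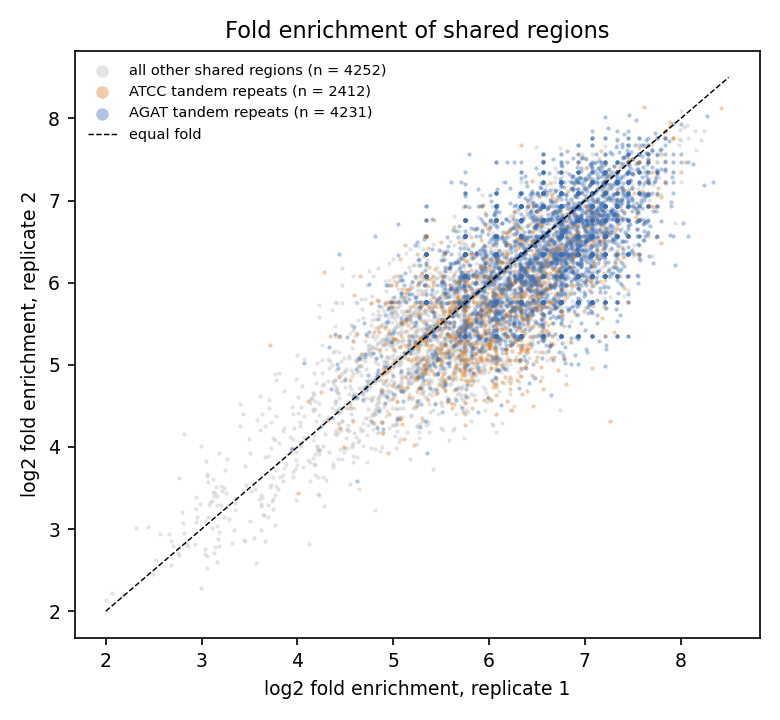
log2 fold enrichment of each shared region in replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 point per region, with the dashed line at equal fold. The 4231 AGAT regions (blue) lie toward the strong end, the 2412 ATCC regions (orange) overlap them, and all other shared regions (grey) extend to the weakest values.

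Peaks seen in a single replicate were weaker than shared peaks. In replicate 1 the median fold enrichment was 70 for shared and 43.3 for single-replicate peaks, a log2 difference of 0.69. In replicate 2 the medians were 59.6 and 40.8, a log2 difference of 0.55. Each difference had a permutation p of 1e-05, the smallest that 100000 permutations can give. Shared peaks held a median of 14 tags against 6 in replicate 1 and 10 against 6 in replicate 2. Of peaks with 5 tags, 19% were shared in replicate 1 and 49.8% in replicate 2, and of those with over 50 tags 98.5% and 97.9%. At the same tag count, peaks on simple tandem repeats were shared more often than other peaks: among 5-tag peaks the shares were 29.2% and 15.1% in replicate 1 (Fisher's exact test, adjusted p = 8.24e-28) and 71.9% and 37.8% in replicate 2 (adjusted p = 3.33e-91). The same direction held in all 7 ranges of tag count in both replicates. These tests treat peaks as independent, though several peaks of a list can overlap the same peak of the other list. Their p-values may therefore be too small, and peak width was not matched.

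The next comparison placed the shared regions along genes and repeats. Intergenic sequence held 60.6% of them (95% Wilson interval 59.7% to 61.6%), introns 35.8% (34.9% to 36.7%), promoters 2.99% (2.69% to 3.33%) and exons 0.578% (0.452% to 0.739%). Simple tandem repeats held 68.6% (67.7% to 69.4%), that is 7472 regions, and the units AGAT and ATCC alone held 38.8% and 22.1%. Tandem repeats were the site of 70.2% of intronic, 69.2% of intergenic and 48.8% of promoter regions, but of 5 of the 63 exon regions. An exon peak can carry an exon label in place of a repeat, so the exon count may be too low. LINE elements held 7.77% of shared regions, LTR elements 3.58% and CpG islands 0.294%. The strands of the units were nearly balanced: in replicate 1, TCTA had 2736 peaks and TAGA 2636, and TGGA had 2362 and TCCA 2217. AGAT peaks had median fold enrichments of 85.9 and 77.9 and ATCC peaks of 67 and 54.4 (not tested on its own). No mock immunoprecipitation was analysed here, so recovery of repeats without YBX1 was not measured. Among rarer units ACC held 591 and 500 peaks, ACCATC 367 and 347, ATC 257 and 203, and ACCC 144 and 96.

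The share of peaks on tandem repeats was higher among peaks with more tags. In replicate 1 it was 27.4% for peaks with 5 tags (95% Wilson interval 26.2% to 28.7%) and 80% for those with 21 to 50 tags (78.5% to 81.5%). In replicate 2 the corresponding shares were 35.2% (33.7% to 36.7%) and 80.6% (78.8% to 82.3%). The 68.6% among shared regions therefore depends on how strong a peak must be to count, and it was 81.8% when the stronger 50% of each list by fold was used.

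**Figure D3:**
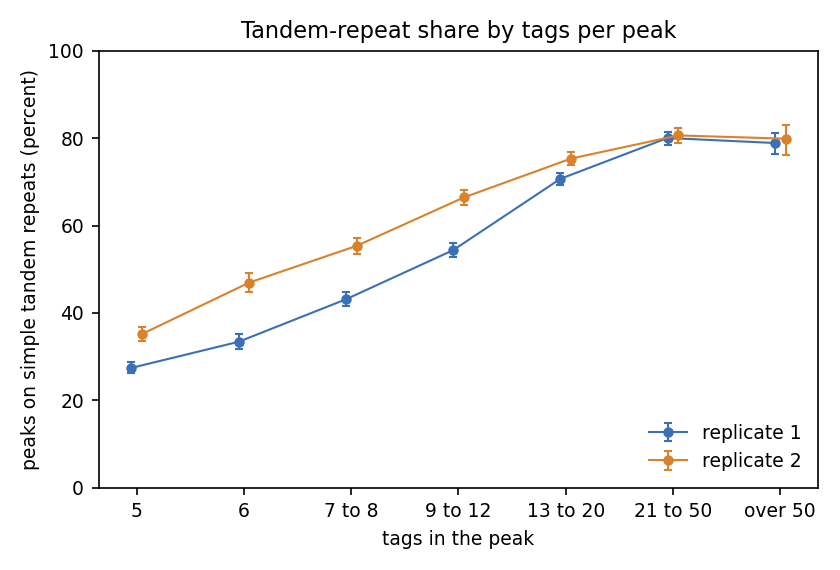
Percent of peaks that lie on simple tandem repeats (vertical axis) by the number of tags in the peak (horizontal axis), for replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. The share is 27.4% and 35.2% at 5 tags and 78.9% and 79.9% above 50 tags.

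The strongest shared regions were tandem repeats in introns or between genes. Of the 20 strongest, 17 lay on simple tandem repeats, 12 in introns and 8 in intergenic sequence, and 3 had no gene named. CFAP61 carried a TGGA repeat region on chromosome 20 from 20317884 to 20318427 with 292 tags in replicate 1 and 249 in replicate 2. An intergenic TAGA repeat near RALGPS2 and MIR4424 on chromosome 1 (178664410 to 178665595) had fold enrichments of 310 and 261. PRKCA, which encodes protein kinase C alpha, had an intronic TGG repeat on chromosome 17 (64795128 to 64795834) at 256 and 272. An intergenic repeat near TGFA, the gene of a ligand of the EGF receptor, on chromosome 2 (70661459 to 70662412) stood at 269 and 243. PIK3R5, a regulatory subunit of phosphoinositide 3-kinase gamma, had an intronic TAGA repeat on chromosome 17 (8828211 to 8829082) at 243 and 245. Introns of GRAMD4, IFFO2, SLC6A12, SPNS3, TRPV3, MRGPRF-AS1 and LOC643542 held further regions of this group, as did intergenic sequence near HMP19 and near RGPD5, RGPD8, ZC3H6 and ZC3H8. The lower fold enrichments of these 9 regions lay between 216 and 237. The 3 regions outside annotated tandem repeats lay in introns of RGS9 (263 and 239) and MON1A (302 and 230) and between genes in the pseudoautosomal part of X near IL3RA, the interleukin-3 receptor alpha chain, and SLC25A6 (283 and 231); most peaks of that part of Y had an X peak at the matching place. The 3 without a named gene were repeats on chromosomes 6, 14 and X.

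Genes with the largest numbers of shared regions in their promoter, exons or introns, named after their values were seen, were CDH4 with 47, SORCS2 with 26, CAMTA1 with 22 and PTPRN2 with 20. Gene length was not taken into account. The strongest regions classed as promoter in both replicates, likewise chosen after their values were seen, lay at TCTA and TAGA repeats of C17orf98 (chromosome 17, 36999069 to 36999207, fold enrichment 202 and 177) and ABCA6 (chromosome 17, 67139962 to 67140063, 166 and 156). Some exon regions without a repeat label were also picked out after their values were seen. Each peak carries a single label, and that of an exon peak can name the exon in place of a repeat. A repeat is therefore not excluded at these regions. KMO, which encodes kynurenine 3-monooxygenase, had one (chromosome 1, 241755984 to 241756112) with fold enrichments of 202 and 136. KCNJ5, a potassium channel gene, had one of 296 and 194 tags (chromosome 11, 128785528 to 128786393).

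The study's own genes carried few peaks. MKNK1, the kinase MNK1 that acts downstream of ERK, had 0 peaks in either list, and MAPK3, which encodes ERK1, had 0. YBX1 had 1 exon peak in each replicate, but at different places: exon 7 of 8 in replicate 1 (chromosome 1, 43166612 to 43166693, 7 tags, fold enrichment 30.6) and exon 5 of 8 in replicate 2 (43162526 to 43162581, 5 tags, fold enrichment 25.1). JAK2 had 1 intronic peak in replicate 1 alone, on an L1ME3 element of chromosome 9 (5059208 to 5059277, 12 tags). The annotation also named it for intergenic peaks at 2 places found in both replicates, at 5189584 to 5189661 (13 tags in replicate 1) and from 5200271 to 5200797. The strongest peak of that second place had 106 tags in replicate 1 and 82 in replicate 2. The genes with 0 peaks are not shown to be free of YBX1, since the weakest peaks listed held 5 tags.

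The gene lists asked whether genes of a process named by any peak carried a shared region more or less often than other genes, of which 66.7% did. Of the 34 MAPK-ERK and MNK signalling genes, 12 were named and 7 of these had a shared region (Fisher's exact test, odds ratio 0.699, adjusted p = 0.799). The strongest were intergenic repeats near the phosphatase genes DUSP5 (fold enrichment 197 and 282), PTPN11 (146 and 113) and DUSP6 (90.9 and 122), followed by an intron of NF1 (74.7 and 68.5). Of the JAK-STAT genes, 12 of 17 had one (odds ratio 1.2, exact test, adjusted p = 1), led by introns of STAT5B (116 and 142) and TYK2 (117 and 94.2) and by intergenic repeats near SOCS5 (111 and 81.4) and STAT4 (107 and 80.7). Promoter regions were shared for TYK2 and IFNAR1 among them, chosen after their values were seen.

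Among the blood cell lists, of the erythroid genes 14 of 15 had a shared region (odds ratio 7, Fisher's exact p = 0.0278, adjusted p = 0.157), with 31 of their 38 regions on tandem repeats. Of the 14 genes, 4 were globin genes, pointed out after their values were seen, and all 4 were named for the same intergenic TAGA repeat of chromosome 11. At a p-value of at most 1e-10 the list had 11 of 15 (odds ratio 0.969, exact test, adjusted p = 1), and with peaks counted the odds ratio was 1.7. ZFPM1, the GATA1 cofactor FOG1, had 19 (strongest at 148 and 136), and BCL11A, the repressor of fetal globin, had 6 (strongest at 121 and 136). GYPC, a gene of the red cell membrane, had 1 (109 and 101). Haematopoietic transcription factors had one in 11 of 12 cases (odds ratio 5.5, exact test, adjusted p = 0.232), among them GATA2 (160 and 117), GFI1B (108 and 95.2) and IRF8 (139 and 87.9). Megakaryocyte and platelet genes had one in 4 of 10 cases (odds ratio 0.333, exact test, adjusted p = 0.25): VWF (170 and 224), GFI1B, RUNX1 (89.4 and 77.8) and FLI1 (45.1 and 33.2).

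Lists of general cell functions did not pass the test either. Among splicing factors, 10 of 18 had a shared region (odds ratio 0.624, exact test, adjusted p = 0.649), in no case in the gene itself. The strongest lay near SRSF5 (130 and 121), SRSF3 (91.5 and 134), U2AF2 (122 and 89.7) and SF3A2 (67.4 and 68). Y-box and cold-shock domain genes had one in 2 of 3 cases, CSDC2 (80.9 and 122) and LIN28B (60.2 and 72.9), with an adjusted p of 1 by Fisher's exact test. Ribosomal protein genes had one in 10 of 19 cases (odds ratio 0.554, exact test, adjusted p = 0.513), the strongest near RPL3 (162 and 150), RPL26 (121 and 136), RPL24 (148 and 96.3) and RPL36 (107 and 67.8). Translation initiation genes had one in 9 of 16 cases (odds ratio 0.642, exact test, adjusted p = 0.761), near EIF4A1 (180 and 160), EIF4G2 (144 and 122), EIF1 (205 and 103) and EIF4B (77.3 and 66.3). Cell cycle and replication genes had one in 13 of 22 cases (odds ratio 0.721, exact test, adjusted p = 0.798), led by an intron of TYMS, the thymidylate synthase (189 and 163), and by sequence near MCM5 (121 and 122), AURKB (113 and 122) and CCNE1 (134 and 100.4). The mitochondrial respiratory chain had one in 14 of 20 cases (odds ratio 1.17, exact test, adjusted p = 1), near ATP5F1A (172 and 160), COX8A (189 and 150), COX4I1 (139 and 87.9, the region also named for IRF8) and COX5B (80.9 and 81.6).

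DNA repair genes had a shared region in 3 of 11 cases (odds ratio 0.187, Fisher's exact p = 0.00875, adjusted p = 0.14), among them DDB2 (121 and 136) and RAD50 (80.9 and 68). At a p-value of at most 1e-10 the list had 2 of 4 (odds ratio 0.352, exact test, adjusted p = 0.746). Canonical histones had one in 5 of 13 cases (odds ratio 0.312, Fisher's exact p = 0.0396, adjusted p = 0.158). H2AC11, H2BC11, H2BC12 and H4C9 were all named for the same intergenic TCTA repeat of chromosome 6 (27041309 to 27041444, 123 and 87), and H2AC25 was the fifth. Of the lists from other cell types, neuronal genes had one in 15 of 16 cases (odds ratio 7.51, Fisher's exact p = 0.0295, adjusted p = 0.157), hepatocyte genes in 6 of 8 (odds ratio 1.5, exact test, adjusted p = 1) and lymphoid genes in 13 of 18 (odds ratio 1.3, adjusted p = 1). Among them were ELAVL4 (151 and 144), SYT1 (121 and 136) and SCN2A (157 and 113) of neurons, CYP2E1 (135 and 81.6) and CYP3A4 (67.4 and 81.6) of liver, and GATA3 (189 and 167), MS4A1 (156 and 163), CD4 (128 and 153) and BLK (135 and 121) of lymphocytes. By Fisher's exact test 0 of the 16 lists passed an adjusted p of 0.05, and 4 had an unadjusted p below it. At a p-value of at most 1e-10 the neuronal list had 12 of 15 (odds ratio 1.41, exact test, adjusted p = 1). With all replicate 2 peaks in place of shared regions, 1 list passed, the canonical histones, which were named less often than other genes (5 of 13, odds ratio 0.16, exact test, adjusted p = 0.0226). With all replicate 1 peaks the histones stood at 13 of 13 against 91.3% of other genes (exact test, adjusted p = 0.882), and with the stronger 50% by fold at 5 of 5.

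Shared regions were unevenly spread over chromosomes. Chromosome 19 held 454 against 208 expected from its length (ratio 2.19, exact binomial test, adjusted p = 3.88e-49), chromosome 21 held 339 against 169 (ratio 2, adjusted p = 6.78e-30), Y 303 against 208 (ratio 1.46, with its pseudoautosomal regions mostly listed on X as well) and chromosome 8 held 703 against 514 (ratio 1.37, adjusted p = 3.21e-15). X held 314 against 547 (ratio 0.575, exact test, adjusted p = 2.62e-27) and chromosome 14 held 259 against 377 (ratio 0.687, adjusted p = 3.6e-10). In replicate 1, 340 of 704 X peaks lay in the first pseudoautosomal region, as did 295 of 533 in replicate 2. The rest of X was therefore sparser than its ratio shows. In all, 10 chromosomes lay above and 11 below their expected share at an adjusted p of 0.05, and chromosomes 9, 17 and 18 did not pass. Unsequenced stretches count toward the lengths and raise the expected numbers, among others on chromosomes 13, 14 and 15. The test also treats regions as independent, which neighbouring regions of a cluster are not, so its p-values may be too small. With the stronger 50% of each list by fold, 6 lay above and 7 below.

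**Figure D4:**
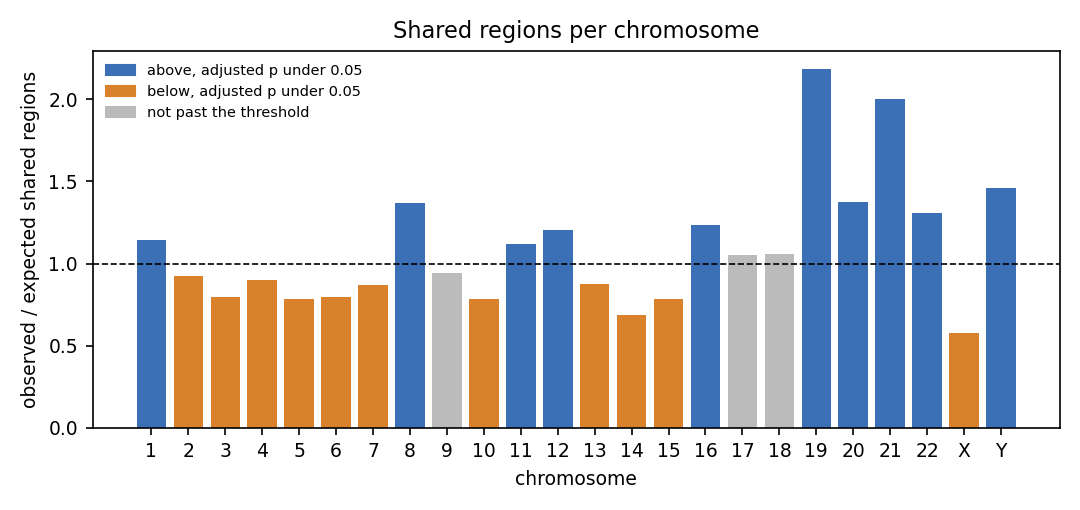
Ratio of observed to expected shared regions (vertical axis) for each chromosome (horizontal axis), where the expected number follows chromosome length with unsequenced stretches included. The dashed line marks a ratio of 1. Blue bars lie above and orange bars below at an adjusted p of 0.05 (exact binomial tests), and grey bars did not pass; chromosome 19 reaches 2.19 and X lies lowest at 0.575.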

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

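All tests of explanations in this part were chosen after the result was seen. Peaks on alternative haplotype contigs, which the comparison of chromosomes and the 20 strongest regions leave out, numbered 39 in replicate 1 and 43 in replicate 2. No comparison reports on them by themselves. Contigs of the chromosome 6 haplotypes carried 28 of them in replicate 1 and 33 in replicate 2, with median fold enrichments of 67.4 and 54.4. Chromosome 17 haplotypes carried 10 and 8, and chromosome 4 haplotypes 1 and 2.

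A first pattern was the concentration of peaks on a few tandem repeat units. Repeat copies missing from the reference would add reads to ChIP and input alike, and a pile-up whose fold enrichment times width exceeds 1000 would then lift the input average over 1 kb above the genome-wide level. Of 11666 such tandem repeat peaks in replicate 1, 48.9% lay at the genome-wide background, as did 45.7% of 10116 in replicate 2. This argues against missing copies as the cause for the peaks at that background and leaves the others open. The product applies the fold at the summit to the whole width, which overstates a pile-up. Nearly all tandem repeat peaks exceeded 1000 (of 11718 in replicate 1 and 10184 in replicate 2), so the rule sets few apart. How far the regional input level sets these shares was not tested. Binding set by the sequence CATC in the repeat unit, a core known from YBX1 binding to RNA, is a biological hypothesis; units without CATC held 55.2% of tandem repeat peaks in replicate 1 and 57.6% in replicate 2, which argues against CATC as the whole cause, while the log2 difference of median fold enrichment, units with CATC minus those without, of -0.30 and -0.36 mostly restates ATCC against AGAT repeats. Recovery of these repeats without YBX1 stays open, because no mock immunoprecipitation was analysed here.

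Another pattern was that peaks of the first pseudoautosomal region, which X and Y share, appear on both chromosomes. Reads that fit both places and were kept may account for it: 83.8% of 328 Y peaks in replicate 1 and 82.9% of 293 in replicate 2 had an X peak within 100 bp at the matching position, 50 kb apart in coordinates. At 40 other shifts the highest share was 12.3%. The excess of shared regions on Y therefore counts some regions again that X holds too. No biological explanation was tested.

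A further pattern was the uneven density of peaks along the genome. More copies of a chromosome in HEL cells would raise ChIP and input reads together, which would leave fewer peaks at the genome-wide background where peaks are dense. Across the 22 autosomes, the share of replicate 1 peaks at that background and shared regions per Mb had a Spearman's rho of -0.256 (permutation p = 0.25) and a Pearson's r of -0.324 (p = 0.142), or -0.364 without the 2 chromosomes farthest from the median. Across 271 windows of 10 Mb with at least 20 peaks in each replicate, with the share from replicate 1 and peak numbers from replicate 2, rho was -0.292 (permutation p = 1e-05, the smallest possible), -0.354 with the replicates exchanged and -0.179 from ranks centred within chromosomes, and neighbouring windows are not independent. Copy number therefore stays open as a partial cause, as does the density of tandem repeats on each chromosome, which was not tested.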

How the results depend on the processing

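The shift of replicate 2 peaks along chromosomes, the correlation over regions at the genome-wide background, the values without X, Y and alternative contigs, and the gene list alternatives by position class, background and peak count were chosen after seeing the data. The shares of peaks found in both replicates, the correlations of strength and the greater strength of shared peaks kept their direction and passed the threshold under each alternative run for them. Shares ranged from 39.3% to 71.3% in replicate 1 and from 52% to 87.8% in replicate 2 and Spearman's rho from 0.558 to 0.732. Most of the values that follow lay beyond the counting interval of the share or over 1.5 times from the count, and the cause was not tested; promoters at 3.28% and introns at 36.4% lay within it. With the stronger 50% of each list by fold, promoters held 2.47%, exons 0.392%, intergenic sequence 62.1% and tandem repeats 81.8%, and 6 chromosomes lay above and 7 below their expected share. At a p-value of at most 1e-10, exons held 0.449% and tandem repeats 79.5%. Tandem repeats held 71.2% with an overlap of 50% of both peaks and 74.2% with summits within 200 bp. Without X, Y and alternative contigs, introns held 37.1%, intergenic sequence 59.3% and tandem repeats 67.6%. All peaks of a single replicate, in place of shared regions, gave promoters 3.28% to 3.42%, exons 0.874% to 0.901%, introns 36.4% to 36.9%, intergenic sequence 58.9% to 59.3% and tandem repeats 51.2% to 58.9%, and 0 to 1 gene lists past the threshold (the canonical histones, lower with replicate 2 peaks and not with replicate 1 peaks). The other alternatives for gene lists gave 0 lists. A false discovery rate of at most 1% removed no peak, so it tests nothing. Of the 20 strongest regions, 6 were no longer shared at an overlap of 50%. Their folds are deposited values that a filter cannot change, so 93 of 94 values were identical by construction. Windows around gene starts, gene length and gene numbers per chromosome were not run, since they need an annotation of the build. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Peaks of few tags were shared least: 19% of replicate 1 and 49.8% of replicate 2 peaks with 5 tags; whether more depth would change this was not tested.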

Other observations

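All tests in this part were chosen after the data were seen. Shared regions were dense near chromosome ends, and the repeat units differed in this. Of 10262 shared regions on autosomes, 16.4% lay within 5 Mb of an end, with the short-arm ends of chromosomes 13, 14, 15, 21 and 22 not counted as ends, against a mean of 7.34% and a highest value of 7.9% over 100 random placements on the same chromosomes (permutation p = 0.0099, the smallest possible). ATCC repeats had 27.9% of their 2294 regions there and AGAT repeats 7.29% of their 3854 (Fisher's exact test, p = 3.11e-103). ACCATC repeats had 42.5% of 174 regions near an end and ACC repeats 20.9% of 297. The placements did not keep regions on tandem repeats, and the positions of all such repeats in the genome were not used. These values therefore cannot separate YBX1 binding near chromosome ends from where the repeats themselves lie.

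Clusters of peaks with unequal counts in the replicates were seen among peaks named for the same gene, and were listed here for that reason. The annotation named RNF187 on chromosome 1 for 33 peaks of replicate 1 and 92 of replicate 2, nearly all in CpG islands, between 228608221 and 228777873. The 92 peaks of replicate 2 lay between 228744342 and 228777758. Whether this cluster has to do with RNF187 itself was not tested. Around REXO1L2P on chromosome 8, a pseudogene of a tandemly repeated gene family, replicate 1 had 57 and replicate 2 had 97. The difference was not tested, since neighbouring peaks of a cluster are not independent. Median fold enrichments were low, at 15.5 and 14.4 for the peaks named for RNF187 and at 10.2 and 9.38 around REXO1L2P. Of these peaks, 0 lay at the genome-wide background of the input.

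The part of chromosome 9 that carries JAK2 differed from the rest of that chromosome in the input level under its peaks. In its first 20 Mb, 1.22% of 245 replicate 1 peaks and 0% of 173 replicate 2 peaks lay at the genome-wide background, whereas beyond 30 Mb the shares were 75.7% of 649 and 76.7% of 477. Other parts of the genome had shares as low: in replicate 1, 0.568% of 1233 peaks in the first 90 Mb of chromosome 1, 0.53% of 1132 peaks beyond 40 Mb on chromosome 8, and 0.692% on chromosome 21. X had 91.8%. Fold enrichment divides by the local input, so fold values of peaks near JAK2 and of peaks on X are not on an equal footing. Over the 271 windows of 10 Mb, the shares of the replicates correlated with Pearson's r of 0.969, as both use the same input.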
